A study of Mus musculus with 40 samples.

How the data were processed

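Messenger RNA of mouse skeletal muscle was measured by sequencing. Per the labels' protocols, quadriceps and gastrocnemius were snap frozen, RNA was extracted with TRI-Reagent and a column kit, and libraries were made with a stranded, polyA-selecting TruSeq kit. The labels place the 40 libraries in 12 groups, 8 of 3 quadriceps libraries and 4 of 4 gastrocnemius libraries. The library descriptions carry a different tag for each, read here as separate animals. Each library was sequenced on 2 lanes, and the table holds a column for each lane, 80 in all.

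The values are estimated counts per gene, which the authors deposited for each lane. Of the values below 6 that do not round to 0, 85.7% lie within 0.1 of a whole number, but no nonzero value is exactly whole. Per the submitters' processing notes, bcl2fastq 2.20.0.422, kallisto 0.46.2 and DESeq2 1.26.0 were used, with the builds GRCm38.p6 and mm10. How transcript estimates were summed to genes, and which annotation was used, is not given in the sources used here. The table has 23621 rows, of which 3288 are 0 in every column. Gene identifiers were matched to symbols and GRCm38.p6 coordinates in a RefSeq gene table, and 23614 matched. The 7 others, which held 0.00139% of the counts, went through the filter and the tests like any other row. kallisto divides reads that fit several transcripts among them by a model, so near-identical genes such as Hspa1a and Hspa1b are uncertain as single genes.

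The 2 lanes of a library were summed and the sums rounded to whole numbers. Totals ran from 27352875 to 79491649 counts, and the library with the lowest total, treadmill +0h ZT0 replicate 3, had 10327419 and 17025769 on its lanes. No 2 libraries of a group differed by as little as sampling noise.

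Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3; robust fit, TMM normalization), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The default filter on low counts (minimum count 10) left 15097 genes in quadriceps and 14523 in gastrocnemius, and all libraries of a tissue entered 1 fit. Adjusted p values in the text come from this test unless a list is named. Fold changes are log2 values with their standard errors, and levels are CPM, computed here from the summed counts and TMM-scaled library sizes, as mean ± SD. The comparisons were treadmill +0h against sedentary muscle at the start of the session (ZT0 or ZT12), +3h against sedentary muscle at ZT4 or ZT16, the differences of these responses between sessions, any difference among the 4 sedentary groups (an F test), sedentary ZT12 against ZT0, day against night wheel access at ZT4 and at ZT16, ZT16 against ZT4 within each schedule, and the difference of those time effects. The +0h comparison of the ZT0 session and the sedentary ZT12 comparison use the same sedentary ZT0 libraries, so no overlap between them was computed. Overlaps given beside the count that independent lists would share are between comparisons that share no library. Genes shared between a comparison and its alternative, such as another sedentary control, come from partly the same libraries and have no such count.

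A total of 32 lists was fixed before the data were examined. The 21 gene lists were immediate early genes, PGC-1 and nuclear receptor programme, oxidative phosphorylation, fatty acid use, lipogenesis and sterol synthesis, glucose and glycogen handling, heat shock and chaperones, endoplasmic reticulum and integrated stress response, glucocorticoid responsive genes, protein degradation and autophagy, core clock, hypoxia and angiogenesis, cytokines and inflammation, myokines, mechanical stress and myogenic regulation, antioxidant response, ribosome biogenesis, amino acid catabolism, slow fibre, fast fibre and mitochondrially encoded genes. The 11 marker lists were adipocyte, erythroid, neutrophil, macrophage, lymphocyte, endothelial, fibroblast and matrix, smooth muscle and pericyte, Schwann cell and nerve, satellite cell and tendon. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 32 lists of a comparison, and again with the correlation estimated for each list. The glucocorticoid list shares 4 genes with protein degradation, 2 with the antioxidant list, 2 with amino acid catabolism, 1 with immediate early genes and 1 with the core clock; the hypoxia list shares 3 with the endothelial markers, and the mechanical stress list 2 with immediate early genes. A list's score in a library is the mean log2 CPM of its genes.

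Genes to name were fixed by a rule: the 8 largest rises and 8 largest falls among genes that passed, had an average log2 CPM of at least 1 and did not overlap between the libraries of the 2 groups; up to 4 genes with the smallest p of each list described; Ppargc1a, Nr4a3, Pdk4, Arntl, Nr1d1, Dbp, Per1, Per2 and Cry1; the 8 smallest p for each difference of responses and the 12 smallest for the test across the sedentary groups. The text names part of what the rule allows, and rises and falls called largest are so within these limits.

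The alternatives chosen before the data were examined were DESeq2 (1.42.0), DESeq2's size factors in edgeR, no filter on low counts, a fit of the compared groups alone, the replicate number as a factor, the first lane alone, leaving out each replicate in turn and, for the +3h responses, sedentary muscle from the start of the session as the control. Chosen after seeing the data were sedentary ZT4 muscle in place of ZT0, and the slow fibre, adipocyte or endothelial score as a covariate.

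The scripts were tested on simulated data, drawn from the real means and library sizes with 200 genes changed by log2 folds of 0.5, 1 and 2. The genes of lowest level were left out when the changed genes were drawn, so the shares recovered do not cover them. In edgeR the shares recovered were 61.2%, 94.0% and 100% for +3h against sedentary muscle in the ZT12 session (14967 genes in the step), 29.9%, 79.1% and 95.5% for the difference of the +3h responses (14967 genes), 55.2%, 89.6% and 97.0% for the sedentary time points (14947 genes), 76.1%, 98.5% and 100% for day against night wheel access at ZT4 (14405 genes) and 47.8%, 94.0% and 98.5% for the difference of the wheel time effects (14405 genes). Unchanged genes made up 5.56%, 4.23%, 4.73%, 3.18% and 5.33% of the calls in these 5. DESeq2's calls held 14.1%, 13.0% and 15.1% unchanged genes in the first 3 (15097 genes); this was above the bound first set for the self-test, which was then applied to edgeR alone, and DESeq2 serves here only as an alternative. In the simulation of the ZT12 session the unchanged +3h comparison of the ZT0 session gave 0 calls, and camera called the 1 raised list and 0 of 20 unchanged lists of 20 genes. The simulated genes varied independently of one another, so this did not test camera on lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.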

Results

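Messenger RNA was sequenced from skeletal muscle of C57BL/6 mice in 40 libraries. The 24 quadriceps libraries formed 8 groups of 3 mice. Sedentary mice were sampled at zeitgeber time (ZT, counted in hours from lights on) 0, 4, 12 and 16. Other mice ran on a treadmill to exhaustion in a session at ZT0 or ZT12 and were sampled at the end of the run (+0h) or 3 h later (+3h). The 16 gastrocnemius libraries formed 4 groups of 4 mice that had access to a running wheel by night or by day and were sampled at ZT4 or ZT16. Total estimated counts per library ran from 27352875 (treadmill +0h ZT0 replicate 3) to 79491649 in quadriceps and from 45010256 to 70033483 in gastrocnemius. After low counts were filtered, 15097 genes were tested in quadriceps and 14523 in gastrocnemius.

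**Figure D1:**
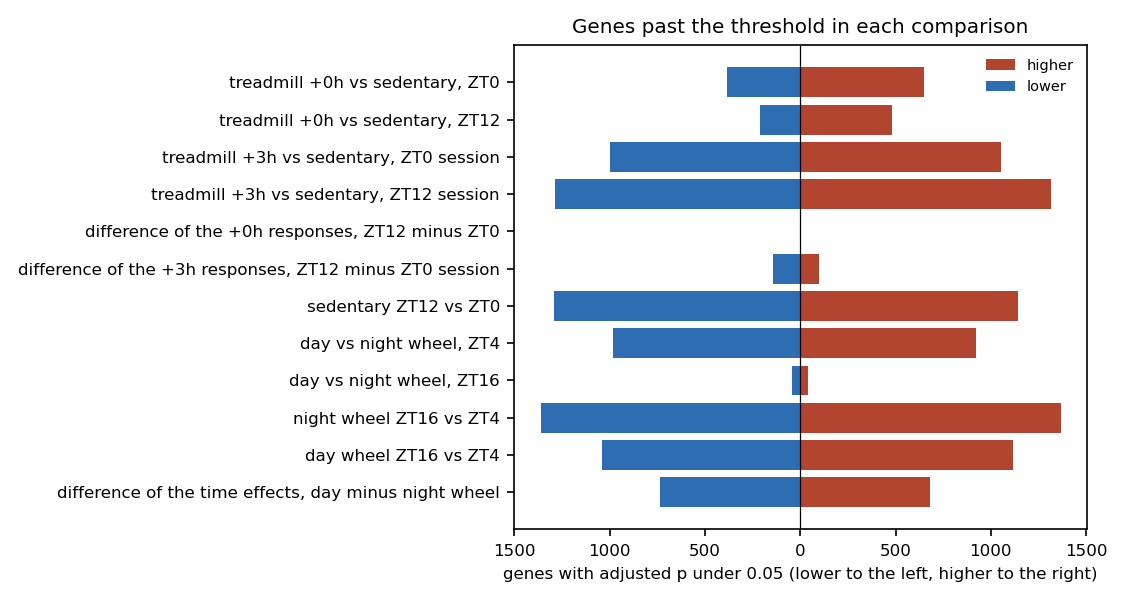
Number of genes that passed an adjusted p of 0.05 in each comparison that has a direction, with higher genes to the right and lower ones to the left; bars start at 0 and the axis counts genes. The sums of both bars run from 0 genes for the difference of the +0h responses to 2729 for night wheel muscle at ZT16 against ZT4.

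The first question was how a run at the start of the light phase acted on the muscle at once. Immediate early genes, which cells switch on within minutes of a stimulus, led the rises at +0h of the ZT0 session against sedentary ZT0 muscle. Junb (gene identifier 16477, chromosome 8, 84976909 to 84978748, GRCm38.p6) stood at 146 ± 15.4 CPM after the run and 5.10 ± 0.372 CPM in the sedentary ZT0 mice (SD, n = 3 each). Its log2 fold change was 4.85 (SE 0.51, adjusted p = 6.5e-05). Fosb rose by 6.15 on the log2 scale, Egr1 by 4.70, Fos by 4.32, Nr4a3 by 4.16 and Arc by 3.97. Of the 28 measured immediate early genes, 22 rose and 6 did not pass, with 26 raised when adjusted over the list alone (camera adjusted p = 1.1e-45; adjusted p = 0.016 with an estimated correlation).

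Genes of the endoplasmic reticulum and integrated stress response rose at the same time, 16 of 25, or 17 adjusted over the list alone (camera adjusted p = 5.9e-16; adjusted p = 0.016 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, rose by 0.73 (SE 0.11, adjusted p = 3e-04) and Hyou1 by 0.61 (SE 0.078, adjusted p = 0.00010). Of 23 glucocorticoid responsive genes, 13 rose, also when adjusted over the list alone (adjusted p = 0.024 with an estimated correlation). Among them were the metallothioneins Mt1 (50.2 ± 7.62 against 6.04 ± 0.564 CPM) and Mt2 (log2 fold change 3.70), the phosphatase Dusp1 (2.20) and the growth regulator Ddit4 (4.66), and Per1, a core clock gene, at 129 ± 25.3 against 12 ± 0.451 CPM. Heat shock genes rose in 12 of 27 members, with 19 raised and 1 lowered adjusted over the list alone (adjusted p = 0.18 with an estimated correlation). Hsp90ab1 rose by 0.49 and Hsph1 by 1.03. Of 18 antioxidant genes, 4 rose (adjusted p = 0.060 with an estimated correlation), among them Nfe2l2 by 0.88, and 2 of these 4 were the metallothioneins.

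The adaptor Irs2 rose to 104 ± 30.4 from 21.7 ± 6.92 CPM and the matrix protein Thbs1 to 171 ± 41.7 from 24.2 ± 8.69 CPM. The largest falls were in Aplnr, the apelin receptor (gene identifier 23796, chromosome 2, 85136360 to 85139923), at 2.26 ± 0.606 against 10.6 ± 1.87 CPM (log2 fold change -2.25, SE 0.37, adjusted p = 0.0012), in Has3 (-2.19) and in Myct1 (-1.75, SE 0.21). The hypoxia and angiogenesis list held 2 raised and 5 lowered genes of 25, and Kdr, an endothelial receptor, fell by 0.73. Of 9 endothelial markers 1 rose and 2 fell. Ppargc1a, a regulator of mitochondrial genes (-0.16, SE 0.11, adjusted p = 0.41), and Pdk4 (0.04, adjusted p = 0.96) did not pass.

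Of 13 mitochondrially encoded genes, 11 fell, or 13 adjusted over the list alone, with a median log2 fold change of -0.52 (adjusted p = 0.11 with an estimated correlation). The transcript mt-Co3 stood at 11100 ± 232 CPM after the run and 16900 ± 4330 CPM in sedentary ZT0 muscle. Against the sedentary ZT4 group, a control chosen after seeing the data, the median of this list was -0.05, and mt-Co3 (-0.04) no longer passed. The nuclear oxidative phosphorylation list held 1 lowered gene of 27, or 10 adjusted over the list alone (adjusted p = 0.44 with an estimated correlation). In the same libraries the slow fibre list had a median of -1.95 without a call in edgeR (3 of 11 at an unadjusted p under 0.05, 1 in DESeq2) and Myl3 read 29.7 ± 9.57 against 179 ± 176 CPM. Adipocyte markers were higher without a call in edgeR (8 of 10 at an unadjusted p under 0.05, 2 in DESeq2, 7 adjusted over the list alone), and Cfd read 442 ± 295 against 133 ± 119 CPM. Cfd passed without sedentary ZT0 replicate 2 (2.78) or treadmill +0h ZT0 replicate 2 (2.20). The lipogenesis and sterol synthesis list moved with them, 1 of 20 raised over all genes and 8 adjusted over the list alone (adjusted p = 0.44 with an estimated correlation).

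In all, 1029 genes passed edgeR's quasi-likelihood test at +0h of the ZT0 session, 647 raised and 382 lowered, of which 205 and 66 changed at least 2-fold. The libraries of the 2 groups did not overlap for 984 of them, where chance gives 10% of unselected genes and 24.9% of all tested genes showed it. Genes called on these same libraries are likely to separate by that selection. Here and in the comparisons below, such counts of called genes are therefore a description and no further support. The count fell to 390 without sedentary ZT0 replicate 1, to 444 without treadmill +0h ZT0 replicate 1 and to 529 when only these 6 libraries were fitted. Kdr lost its call without either library (-0.66 and -0.68), Fos without the first (4.33), and Hsph1 (1.02) and mt-Co3 (-0.61) in the fit of 6. With the adipocyte score as a covariate 590 genes passed, and against sedentary ZT4 muscle Fosb (2.25), Egr1 (1.26) and Fos (2.34) did not.

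A run to exhaustion at the start of the dark phase was compared with sedentary ZT12 muscle. Heat shock and immediate early genes led the rises at +0h of the ZT12 session. The inducible heat shock genes Hspa1b (gene identifier 15511, chromosome 17, 34956429 to 34959238) and Hspa1a read 233 ± 124 against 4.20 ± 1.51 CPM and 255 ± 120 against 5.89 ± 1.66 CPM (adjusted p = 0.0073 and 0.0055). The split of reads between these near-identical copies is uncertain. Sedentary ZT12 muscle was itself low against sedentary ZT0 muscle (log2 fold change -3.25 for Hspa1a and -3.54 for Hspa1b). Sedentary ZT16 muscle, without a run, read 63.8, 272 and 382 CPM for Hspa1a. The size of this rise therefore depends on which sedentary group is the control. Heat shock genes rose in 15 of 27 members, or 22 adjusted over the list alone (camera adjusted p = 9.1e-24; adjusted p = 0.054 with an estimated correlation), with Hspa8 at 1480 ± 52.8 against 888 ± 85.0 CPM and Dnaja1 up by 1.88. Of 28 immediate early genes 24 rose and 4 did not pass, with all 28 raised adjusted over the list alone (adjusted p = 0.0071 with an estimated correlation). Fosb rose by 5.24, Nr4a3 by 4.96, Atf3 by 4.84, Junb by 4.59 and Klf4 by 2.86, each with an SE under 1.

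Of 23 glucocorticoid responsive genes 7 rose, or 14 adjusted over the list alone (adjusted p = 0.054 with an estimated correlation): Mt1 by 2.65 (SE 0.25), Mt2 by 3.39 and Errfi1 by 2.40 (SE 0.43). The mechanical stress and myogenic list held 6 raised genes of 22 (adjusted p = 0.42 with an estimated correlation), among them Myog, a myogenic transcription factor, by 1.87 (SE 0.27). The cyclooxygenase gene Ptgs2 rose by 4.09, Thbs1 by 3.78 (SE 0.42) and Irs2 by 2.16 (SE 0.35). The largest falls were again led by Aplnr, at 1.21 ± 0.566 against 5.69 ± 2.01 CPM, followed by Ahr (-1.37), Ednra (-1.33) and Efna1 (-1.23). Of 25 endoplasmic reticulum and integrated stress genes 2 rose, Ppp1r15a among them (1.04, SE 0.15, adjusted p = 0.00046). No mitochondrially encoded gene passed in edgeR (1 of 13 at an unadjusted p under 0.05, 0 in DESeq2; mt-Nd5 -0.23, adjusted p = 0.22), and Ppargc1a and Pdk4 (0.08, adjusted p = 0.93) did not pass either. Adipocyte markers were lower here without a call in edgeR (3 of 10 at an unadjusted p under 0.05, 0 in DESeq2), with a median of -1.40, and the lipogenesis list had a median of -0.45.

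The ZT12 session changed 695 genes at +0h, 482 raised and 213 lowered, 191 and 66 of them at least 2-fold, and 688 had libraries that did not overlap against 20.2% of all tested genes. The count was 380 without sedentary ZT12 replicate 1, 413 without treadmill +0h ZT12 replicate 1, 456 without its replicate 2, 385 in the fit of these 6 libraries alone, where Aplnr (-2.23) lost its call, and 450 with the adipocyte score as a covariate.

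Whether the +0h response depended on the time of the session was tested as the difference of the responses. Different mice ran to exhaustion in each session, and how long they ran was not among the data used here. A difference in the run itself is thus not separated from time of day, at +0h or at +3h. Of the genes called at +0h, 298 rose in both sessions, where independent lists of these sizes would share 20.7, and 65 fell in both (5.39 by independence), with 0 called in opposite directions (21.3 by independence). The 2 comparisons share no libraries, and their fold changes correlated at r = 0.28 across genes, which are not independent replicates. No gene passed the test of the difference in edgeR, although 1912 had an unadjusted p under 0.05 and DESeq2 called 16. Per1 came closest among the clock genes (-2.48, SE 0.52, adjusted p = 0.26), followed by Arrdc2 (-2.74, SE 0.58). Per1 read 12 CPM in sedentary ZT0 mice and 129 CPM at +0h of the ZT0 session. In sedentary ZT12 mice and at +0h of the ZT12 session it read 119 and 229 CPM. Adipocyte markers had a median difference of -3.22 (9 of 10 lowered adjusted over the list alone; adjusted p = 0.32 with an estimated correlation) and the lipogenesis list one of -1.19 (11 of 20; adjusted p = 0.43). Without treadmill +0h ZT0 replicate 2, 322 genes passed, Per1 (-2.55) and Arrdc2 (-2.85) among them; Per1 (-2.48) and Arrdc2 (-2.74) also passed in DESeq2, and Per1 in the fit of these 12 libraries. The 65 genes lowered in both sessions became 36 without sedentary ZT0 replicate 1, 34 without treadmill +0h ZT0 replicate 1, 40 without sedentary ZT12 replicate 1, 36 without treadmill +0h ZT12 replicate 1 and 39 without its replicate 2. The 298 raised genes became 185 without sedentary ZT0 replicate 1.

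**Figure D2:**
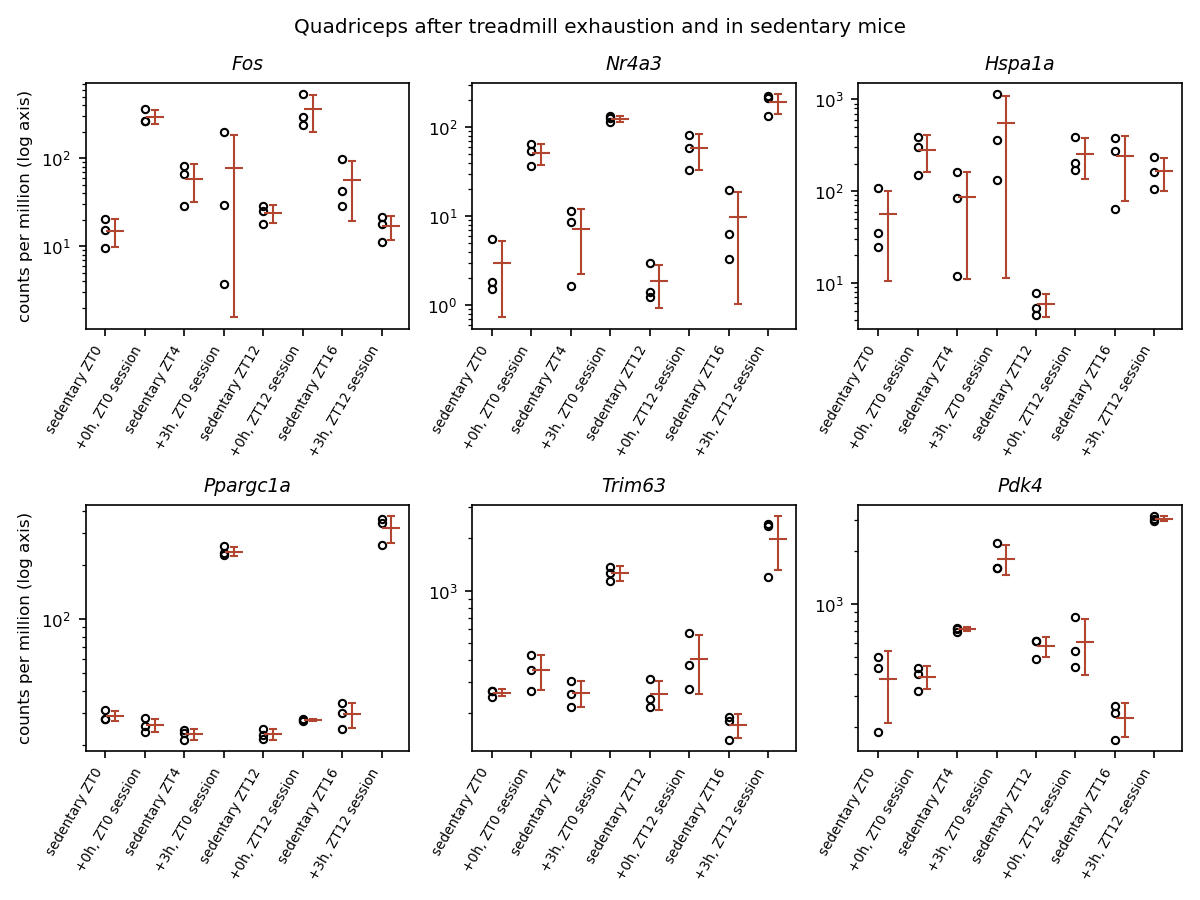
Expression of Fos, Nr4a3, Hspa1a, Ppargc1a, Trim63 and Pdk4 in the 8 quadriceps groups, in CPM on a log axis; points are libraries and bars the mean ± SD of 3 mice. Ppargc1a stood at 237 and 319 CPM at +3h of the ZT0 and ZT12 sessions against 22.9 and 29.6 CPM in sedentary ZT4 and ZT16 muscle.

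The later response was read 3 h after the ZT0 session against sedentary muscle at ZT4, the nearest time of day. Ppargc1a (gene identifier 19017, chromosome 5, 51454249 to 52115853) stood at 237 ± 14.1 against 22.9 ± 1.53 CPM (log2 fold change 3.37, SE 0.12, adjusted p = 2.1e-13). Nr4a3 rose by 4.13 (SE 0.72), Mt2 by 4.37 (SE 0.35) and Mt1 by 3.28 (SE 0.26). Hk2, which starts glucose breakdown, rose to 846 ± 88.4 from 257 ± 11.4 CPM, and Trim63, a muscle ubiquitin ligase, to 1260 ± 122 from 259 ± 44.1 CPM. Heat shock genes rose in 19 of 27 members, or 25 adjusted over the list alone (adjusted p = 0.13 with an estimated correlation), with Bag3 at 279 ± 167 against 105 ± 14.5 CPM. The endoplasmic reticulum and integrated stress list held 15 raised genes and 1 lowered of 25 (adjusted p = 0.017 with an estimated correlation), among them Hsp90b1 by 0.75 (SE 0.083), Hspa5 by 0.70 and Pdia3 by 0.69.

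Of 18 antioxidant genes 6 rose, or 7 adjusted over the list alone (adjusted p = 0.017 with an estimated correlation), led by the metallothioneins and Srxn1, at 203 ± 140 against 24.9 ± 1.75 CPM. Of 23 glucocorticoid responsive genes 11 rose, Zbtb16 by 1.88 (SE 0.21), and of 25 protein degradation and autophagy genes 7 rose, Gabarapl1 by 1.20 (SE 0.15); each list had an adjusted p of 0.13 with an estimated correlation. The 2 lists share 4 genes, Trim63 among them. The mechanical stress list held 11 raised genes of 22 (adjusted p = 0.27 with an estimated correlation), with wide spread: Ankrd1 read 129 ± 168 CPM and the actin-binding Xirp1 1800 ± 1730 against 140 ± 3.67 CPM. Without treadmill +3h ZT0 replicate 1, in which Hspa1a and Fos read highest of the 3, the camera adjusted p of the heat shock and mechanical stress lists went from 2.4e-15 and 1.2e-07 to 2.8e-11 and 0.00022. Among fatty acid genes 4 of 25 rose, Pdk4 by 1.34 (SE 0.29), Ucp3 by 1.33 (SE 0.28) and Cpt1a by 0.54 (SE 0.11). Ribosome biogenesis genes rose in 8 of 24 members (adjusted p = 0.27 with an estimated correlation), the cytokine list held 6 raised and 1 lowered of 22, and 3 of 20 lipogenesis and sterol genes fell, Srebf2 by 0.50 (SE 0.072).

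Immediate early genes had split by then, 6 raised and 4 lowered of 28 (adjusted p = 0.97 with an estimated correlation). The largest falls were in Egr3 (gene identifier 13655, chromosome 14, 70077317 to 70082613), at 0.418 ± 0.297 against 11.1 ± 6.14 CPM, Apold1 (-4.42, SE 0.57), Klf2 (-2.67, SE 0.33) and Dach1 (-2.70, SE 0.19). The sedentary ZT4 group was itself high and variable for some of these genes, and Egr3 did not pass against sedentary ZT0 muscle (-1.39). Trp53i11 fell by 2.08 (SE 0.18). Dbp, a clock output gene, read 16.2, 21.3 and 22.6 CPM in the 3 libraries, taken as at 3.5 h of the day, against 55.0 ± 7.51 CPM in sedentary muscle at 4 h (-1.46, SE 0.15), and Nfil3 rose by 1.91 (SE 0.21); against sedentary ZT0 muscle Dbp was higher (1.23).

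At +3h of the ZT0 session 2052 genes passed, 1051 raised and 1001 lowered, 291 and 119 of them at least 2-fold, and 1977 had libraries that did not overlap against 30.7% of all tested genes. Against sedentary ZT0 muscle 2032 passed, 1264 of them among the 2052 and 1 of these in the opposite direction. In the fit of these 6 libraries alone 1105 passed, and Nr4a3 (4.12), Srxn1 (3.02), Bag3 (1.41), Ankrd1 (4.15) and Xirp1 (3.68) did not.

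After the ZT12 session the +3h libraries were set against sedentary ZT16 muscle. Pdk4, which limits carbohydrate oxidation (gene identifier 27273, chromosome 6, 5483351 to 5496278), stood at 3070 ± 95.1 against 225 ± 49.5 CPM (log2 fold change 3.77, SE 0.31, adjusted p = 2.8e-07). Trim63 read 1990 ± 683 against 170 ± 26.5 CPM and Fbxo32, another ubiquitin ligase, 1200 ± 108 against 196 ± 42.5 CPM. Ppargc1a rose by 3.43 (SE 0.12, adjusted p = 1.5e-13), Nr4a3 by 4.27 (SE 0.71) and Tmem140 by 3.21 (SE 0.20).

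Protein degradation and autophagy genes rose in 15 of 25 members, or 17 adjusted over the list alone (camera adjusted p = 1.1e-20; adjusted p = 0.0077 with an estimated correlation), among them Gabarapl1 by 1.88, Gadd45a by 1.87 and Cblb by 1.09. The glucocorticoid responsive list, which shares 4 genes with it, held 15 raised and 1 lowered of 23 (adjusted p = 0.062 with an estimated correlation), with Mt1 up by 3.65, Mt2 by 4.54 and Klf15 by 1.31. Of 18 antioxidant genes 6 rose (adjusted p = 0.034 with an estimated correlation), Srxn1 by 2.27 (SE 0.33) and Gclc by 0.48. Fatty acid genes rose in 7 of 25 members, or 8 adjusted over the list alone (adjusted p = 0.45 with an estimated correlation): Angptl4 by 3.89 (SE 0.81), Ucp3 by 2.33, Acot2 by 2.07 and Cpt1a by 1.62. In the glucose list 6 rose and 1 fell of 31, Hk2 up by 1.42 (SE 0.13) and Irs1 down by 2.02 (log2 fold change -2.02, SE 0.29).

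Ribosome biogenesis genes rose in 12 of 24 members (adjusted p = 0.42 with an estimated correlation) by small amounts, Ddx21 by 0.40 (SE 0.056) and Npm1 by 0.36. Heat shock genes were split, 1 raised and 2 lowered of 27, with Dnajb5 at -0.34 (SE 0.069), and endoplasmic reticulum and stress genes were at 4 raised and 2 lowered of 25. The mechanical stress list held 8 raised and 3 lowered of 22, Xirp1 at 2.22 (SE 0.52) and Flnc at 1.59, and the cytokine list 7 raised and 1 lowered of 22. Cry2 rose by 1.19 (SE 0.11), and the clock list held 4 raised and 4 lowered of 20. The largest falls included G0s2, an inhibitor of fat breakdown, at 6.04 ± 2.12 against 69.3 ± 33.4 CPM, Kcnf1 (-2.59, SE 0.56) and Dach1 (-2.42, SE 0.19). Of 6 neutrophil markers 2 rose, S100a9 at 0.754 ± 1.13 against 0.0285 ± 0.00398 CPM, a rise that 1 library carried (1.78 and no call without treadmill +3h ZT12 replicate 1). Satellite cell markers were at 3 raised and 1 lowered of 6, Pax7 falling by 1.26.

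The ZT12 session changed 2602 genes at +3h, 1314 raised and 1288 lowered, 271 and 170 at least 2-fold, and 2515 had libraries that did not overlap against 32.9% of all tested genes. Without treadmill +3h ZT12 replicate 3 the count was 1724. Against sedentary ZT12 muscle 2869 passed, of which 1398 were among the 2602 and 17 of these had the opposite direction; Angptl4 (0.94) and Irs1 (-0.59) did not pass.

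The called genes of both sessions overlapped at +3h, with 543 genes raised in both (91.5 by independence), 436 lowered in both (85.4) and 20 called in opposite directions (176.8), and r = 0.43 across genes. Without treadmill +3h ZT0 replicate 2 the 436 became 279. The difference between the sessions passed for 240 genes, 98 with a higher and 142 with a lower value in the ZT12 session. This majority was not stable, with 64 higher and 49 lower in the fit of the compared groups alone. It was 97 and 78 without treadmill +3h ZT12 replicate 1. Leaving out most other libraries kept it, as with 95 and 140 without treadmill +3h ZT0 replicate 2. Banp (gene identifier 53325, chromosome 8, 121947972 to 122029260) had the smallest p (log2 difference -2.46, SE 0.19, adjusted p = 7.3e-07): it read 13.8 and 14.5 CPM at +3h of the ZT12 and ZT0 sessions but 19.7 and 3.75 CPM in sedentary ZT16 and ZT4 muscle. Cecr2 (1.37), Slc43a1 (1.92) and Pnrc1 (1.06) followed. Higher differences in the ZT12 session included Pdk4 (2.44, SE 0.40), Fbxo32 (1.93, SE 0.32), Cpt1a (1.09, SE 0.16) and the kinase Sgk1 (1.42, SE 0.27), with 3 of 25 fatty acid and 2 of 25 protein degradation genes passing (adjusted p = 0.32 and 0.14 with an estimated correlation). Lower differences came in 10 of 25 endoplasmic reticulum and stress genes, Hsp90b1 (-0.70, SE 0.12), Hyou1 (-0.63) and Manf (-1.02) among them, and in 4 of 27 heat shock genes, or 20 adjusted over the list alone (adjusted p = 0.14 with an estimated correlation for each list). Dbp differed by 1.35 and Nfil3 by -1.47, whereas Ppargc1a (0.06, adjusted p = 0.92), Nr4a3 (0.14, adjusted p = 0.97) and Trim63 (1.27, adjusted p = 0.11; it passed in DESeq2 at 1.26 and, at 1.53, without treadmill +3h ZT12 replicate 1) did not pass.

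The calls depended on the choice of sedentary control. With sedentary muscle from the session start as the control, 201 genes passed, of which only 17 were among the 240 and 5 of these had the opposite direction. Pnrc1 and Ppargc1a (0.76) passed, while Pdk4 (0.14), Fbxo32 (1.19), Sgk1 (0.66), Hsp90b1 (-0.36), Hyou1 (-0.25) and Manf (-0.16) lost their calls. The values of Banp (0.69), Cecr2 (-0.35), Slc43a1 (-0.41), Cpt1a (-0.60), Dbp (-2.65) and Nfil3 (0.97) turned direction. The 240 genes became 107, 115 and 140 without sedentary ZT4 replicates 2, 3 and 1, and 129 and 159 without sedentary ZT16 replicates 1 and 3. They became 141 without treadmill +3h ZT0 replicate 1, 109 without treadmill +3h ZT12 replicate 2 and 113 in the fit of these 12 libraries, where Sgk1 (1.41) lost its call. The first lane alone gave 118 and DESeq2 435.

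Time of day without exercise was read across the 4 sedentary groups. Core clock genes led, 18 of 20 passing the test of any difference, or 19 adjusted over the list alone. Dbp (gene identifier 13170, chromosome 7, 45705100 to 45710203) read 8.58 ± 0.957, 55.0 ± 7.51, 120 ± 1.40 and 48.3 ± 7.36 CPM at ZT0, ZT4, ZT12 and ZT16 (adjusted p = 2.8e-10). Arntl, also called Bmal1, read 48.3 ± 2.77, 28.7 ± 4.67, 3.91 ± 0.765 and 15.1 ± 3.64 CPM (adjusted p = 2.1e-09), and its partners Npas2 (adjusted p = 9.1e-09) and Clock (adjusted p = 4.0e-08) were also lowest at ZT12. Nr1d1, a repressor of Arntl, was highest at ZT4 (207 ± 15.2 CPM) and lowest at ZT16 (22.2 ± 4.99 CPM). Per1 was highest at ZT12 (119 ± 16 CPM), Per2 at ZT16 (43.1 ± 4.87 CPM), and Cry1 also passed (adjusted p = 1.3e-05). Outside the clock, Banp was highest at ZT16 (19.7 ± 1.99 CPM) and the carrier Slc25a36 at ZT0 (33.0 ± 2.65 CPM).

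Other lists passing this test in at least 10 members were glucocorticoid responsive genes (15 of 23), heat shock genes (14 of 27), the hypoxia list (13 of 25), ribosome biogenesis (11 of 24) and mitochondrially encoded genes (10 of 13). Glul, which makes glutamine, read 223 ± 24.5 at ZT0 and 723 ± 114 CPM at ZT12, Hspa8 fell between them from 1370 ± 143 to 888 ± 85.0 CPM, and Pdk4 ran from 720 ± 18.9 CPM at ZT4 to 225 ± 49.5 CPM at ZT16. Of 9 endothelial markers, 3 of which the hypoxia list also holds, 7 passed, with Kdr at 63.8 ± 6.84 at ZT0 and 26.9 ± 4.14 CPM at ZT12. In total 2578 genes passed, 644 highest at ZT0, 437 at ZT4, 848 at ZT12 and 649 at ZT16, and 533 spanned more than 2-fold. Without sedentary ZT12 replicate 2, 1558 passed. With the adipocyte score as a covariate, chosen after seeing the data, 1730 passed. That score was 4.87, 5.28, 6.81 and 5.45 at ZT0, ZT4, ZT12 and ZT16. How far differing amounts of adipose tissue added to the genes highest at ZT12 was not tested.

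**Figure D3:**
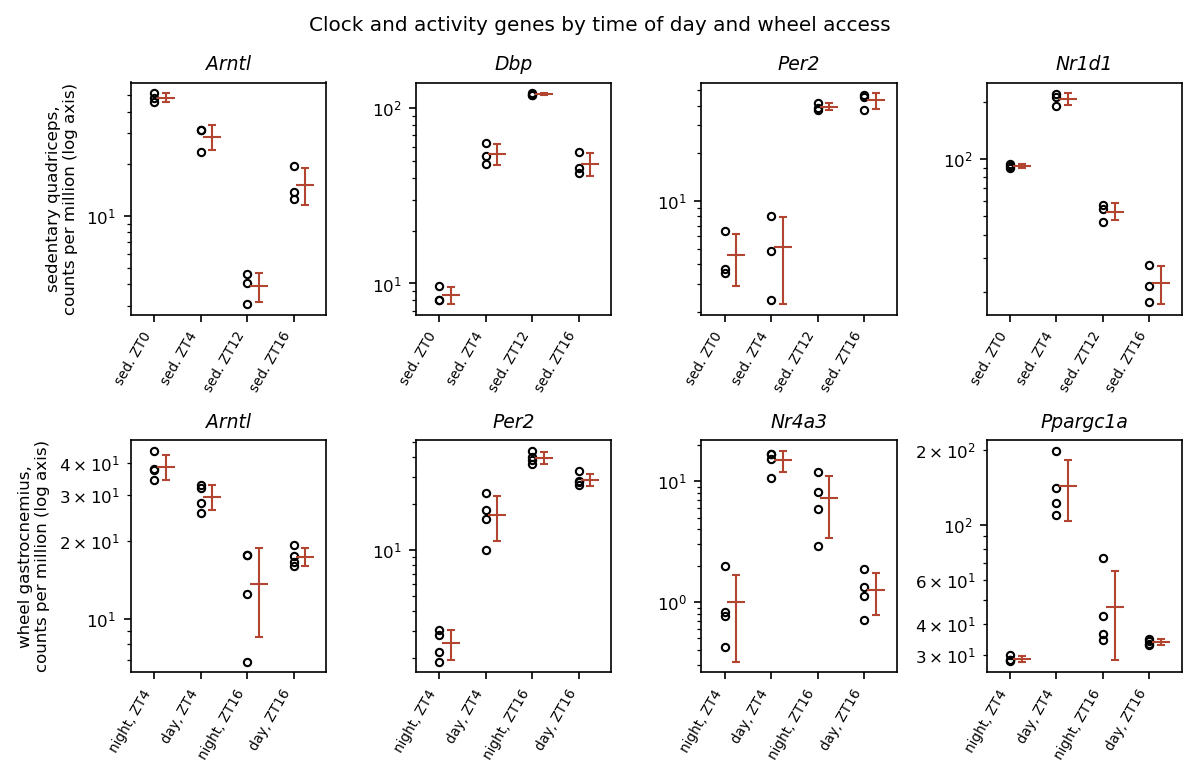
Top, Arntl, Dbp, Per2 and Nr1d1 in sedentary quadriceps at ZT0, ZT4, ZT12 and ZT16; bottom, Arntl, Per2, Nr4a3 and Ppargc1a in gastrocnemius of mice with wheel access by night or by day at ZT4 and ZT16. Axes are in CPM on a log scale, points are libraries and bars the mean ± SD of 3 (top) or 4 mice (bottom). Per2 stood at 16.9 CPM in day wheel and 2.48 CPM in night wheel muscle at ZT4.

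The baselines of the 2 sessions were compared directly as sedentary ZT12 against ZT0. Dbp (3.81, SE 0.16), Per1 (3.31), Per2 (3.12) and Ciart (3.78) rose while Npas2 (-5.32, SE 0.36), Arntl (-3.63, SE 0.19) and Clock (-1.20) fell, and the clock list held 10 raised and 6 lowered of 20 (adjusted p = 0.039 with an estimated correlation). Arrdc2 rose to 200 ± 79.8 from 9.89 ± 0.977 CPM and Ddit4 by 3.76 (SE 0.86). Spon2 fell by 3.80 (SE 0.43), Ppp1r27 by 2.40 (SE 0.21) and Tnfrsf12a by 2.02 (SE 0.34). Of 27 nuclear oxidative phosphorylation genes 17 fell, Cycs by 0.40 (SE 0.084), and 11 of 13 mitochondrially encoded genes fell, mt-Co3 by 0.63 (SE 0.12); these lists had adjusted p = 0.59 and 0.36 with an estimated correlation. Of 9 endothelial markers 7 fell, Kdr by 1.24 and Tek by 0.58 (adjusted p = 0.18 with an estimated correlation), and 10 of 25 hypoxia genes fell and 1 rose, Hif3a by 2.35 (adjusted p = 0.36). Glucocorticoid responsive genes were at 11 raised and 1 lowered (adjusted p = 0.36), heat shock genes at 8 lowered of 27 (adjusted p = 0.49) with Hspa8 down by 0.62, and ribosome biogenesis genes at 8 raised of 24 (adjusted p = 0.36), Nop56 by 0.39. Adipocyte markers rose in 3 of 10 members (adjusted p = 0.59), their mean log2 CPM going from 4.87 ± 1.02 to 6.81 ± 1.22. Of 11 slow fibre genes 1 fell (adjusted p = 0.71 with an estimated correlation), with a mean log2 CPM of 3.73 ± 0.996 against 5.60 ± 1.42, and of 12 fast fibre genes 3 rose (adjusted p = 0.78).

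The comparison called 2436 genes, 1144 raised and 1292 lowered, 208 and 228 at least 2-fold, and 2300 had libraries that did not overlap against 34.5% of all tested genes. The count was 1534 and 1283 without sedentary ZT0 replicates 1 and 3, 1287 without sedentary ZT12 replicate 2, and 1597 in the fit of these 6 libraries, where mt-Co3 (-0.63) did not pass. It was 1144 with the adipocyte score as a covariate (Cycs -0.23 and no call) and 1026 for ZT12 against ZT4, a comparison chosen after seeing the data in which Per1 (1.20), mt-Co3 (-0.06) and Cycs (-0.13) did not pass.

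In gastrocnemius the question was how wheel access by day, the usual rest phase of mice, changed the muscle. At ZT4 the orphan receptor Nr4a3 (gene identifier 18124, chromosome 4, 48045078 to 48086447) stood at 14.9 ± 2.98 CPM in day wheel and 1.00 ± 0.685 CPM in night wheel muscle (SD, n = 4 each; log2 fold change 3.80, SE 0.47, adjusted p = 0.00036). Ppargc1a read 144 ± 39.4 against 28.8 ± 0.760 CPM (2.32, SE 0.23, adjusted p = 0.00011) and Per2 16.9 ± 5.55 against 2.48 ± 0.535 CPM (2.75, SE 0.24, adjusted p = 3.1e-05). Otud1 rose by 2.37, Banp by 2.28, Atf3 by 2.25 and Slc25a25 by 2.49, while Dusp10 (-1.59), Trp53i11 (-1.53), Foxo6 (-1.12) and Wdr6 (-1.10) were lower than in night wheel muscle.

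Heat shock genes rose in 12 of 27 members and 1 fell, Hspa1b at 11.1 ± 2.24 against 2.82 ± 0.542 CPM and Dnaja1 up by 0.83. Immediate early genes rose in 10 of 27, Maff by 0.93, and core clock genes were at 8 raised and 2 lowered of 20, with Bhlhe41 at 29.3 ± 1.32 against 54.6 ± 4.95 CPM. Of 19 genes of the PGC-1 programme 6 rose and 1 fell, Ppara by 1.31. Endoplasmic reticulum and stress genes were at 5 raised and 1 lowered of 25, Hspa5 by 0.36 and Manf by 0.53, glucocorticoid responsive genes at 5 raised of 23, Klf15 by 0.87 and Tsc22d3 by 0.77, and mechanical stress genes at 5 raised of 22, Abra by 1.56 (SE 0.19). Each of these lists had a camera adjusted p of 0.0022 or less, and adjusted p = 0.15 to 0.17 with an estimated correlation. Lipogenesis and sterol genes were split, 2 raised and 7 lowered of 20 (adjusted p = 0.73 with an estimated correlation), Sqle by -1.65 and Scd2 by -0.93. Nfe2l2 rose by 0.62 (SE 0.061).

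Endothelial markers fell in 6 of 9 members, or 7 adjusted over the list alone (adjusted p = 0.15 with an estimated correlation), with Cldn5 at 7.45 ± 1.22 against 14.4 ± 1.51 CPM and Egfl7 down by 0.47 (log2 fold change -0.47, SE 0.065). The mean log2 CPM of the 9 markers was 4.63 ± 0.0943 in day wheel and 4.99 ± 0.0521 in night wheel muscle. Slow and fast fibre, mitochondrially encoded, adipocyte, erythroid, satellite cell and tendon lists held no called gene in edgeR (0 to 1 member of each at an unadjusted p under 0.05, 0 in DESeq2). Arntl (-0.38, adjusted p = 0.27), Nr1d1 (-0.43, adjusted p = 0.11; passed at -0.42 in the fit of these 8 libraries), Dbp (-0.22, adjusted p = 0.44) and Pdk4 (0.33, adjusted p = 0.74) did not pass.

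At ZT4 1907 genes differed between day and night wheel muscle, 923 higher by day and 984 lower, 76 and 56 of them at least 2-fold, and 1691 had libraries that did not overlap, where chance gives 2.86% and 21.1% of all tested genes showed it. The count was 1248 without night wheel ZT4 replicate 2 and 1139 and 1196 without day wheel ZT4 replicates 3 and 4. With the endothelial score as a covariate, chosen after seeing the data, 256 genes passed, 179 higher and 77 lower by day. Among those named the calls of Slc25a25 (2.45), Dusp10 (-1.50), Trp53i11 (-1.23), Maff (0.85), Ppara (1.36) and Klf15 (0.67) ended. So did those of Tsc22d3 (0.72), Sqle (-1.56), Scd2 (-0.48), Cldn5 (-0.34) and Egfl7 (-0.30).

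At ZT16 far fewer genes differed between the schedules, and most of the named ones ran the other way. Immediate early genes were lower in day wheel muscle, 4 of 27, or 17 adjusted over the list alone (camera adjusted p = 1.7e-20; adjusted p = 0.011 with an estimated correlation). Nr4a3 read 1.26 ± 0.477 against 7.25 ± 3.83 CPM (-2.55, SE 0.47, adjusted p = 0.038), Maff 1.41 ± 0.0614 against 2.85 ± 0.559 CPM and Zfp36 fell by 0.52 (SE 0.081). Otud1 fell by 1.22 (SE 0.19, adjusted p = 0.013) and Ccn2 by 0.92 (SE 0.15). Heat shock genes held 1 lowered member, Hspa1b at 5.13 ± 1.17 against 15.8 ± 6.45 CPM, or 17 of 27 adjusted over the list alone (adjusted p = 0.10 with an estimated correlation). Of 20 lipogenesis and sterol genes 1 rose, Insig1, which restrains sterol synthesis, at 12.2 ± 0.844 against 8.51 ± 0.585 CPM (0.52, SE 0.074, adjusted p = 0.0030), with 11 raised and 1 lowered adjusted over the list alone (adjusted p = 0.079 with an estimated correlation). Among other rises were Nhs (1.06, SE 0.17) and Zfp521 (0.51, SE 0.082), and Wdr90 fell by 0.83. Ppargc1a (-0.47, adjusted p = 0.40), Per2 (-0.47, adjusted p = 0.29; passed at -0.48 in the fit of these 8 libraries) and Arntl (0.36, adjusted p = 0.54) did not pass.

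Of the 82 genes called at ZT16, 40 were higher and 42 lower in day wheel muscle, 2 and 6 at least 2-fold, and all 82 had libraries that did not overlap against 6.67% of all tested genes. Of them 46 were called in the opposite direction at ZT4 (5.38 by independence) and 1 in the same. The count was 163, 51 and 29 without night wheel ZT16 replicates 1, 2 and 3, 36, 28 and 19 without day wheel ZT16 replicates 2, 3 and 4, 35 in the fit of these 8 libraries, 369 in DESeq2 and 164 with the endothelial score as a covariate. Nr4a3 lost its call without any 1 of 7 of the 8 libraries (-2.78 to -2.20; it was kept only without night wheel ZT16 replicate 1). Hspa1b lost its call without night wheel replicates 2 or 3 or day wheel replicates 2, 3 or 4 (-1.68 to -1.43), Otud1 (-1.17) and Ccn2 (-0.90) without day wheel replicate 3, Ccn2 (-0.89) also without its replicate 4, and Nhs (1.06) in the fit of 8. Nr4a3 and Hspa1b also lost their calls from the first lane alone (-2.42 and -1.51) and in the fit of 8 (-2.54 and -1.63), and Nr4a3 with no filter on low counts (-2.55).

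The change from ZT4 to ZT16 was then read within each schedule. In night wheel muscle Per2 (gene identifier 18627, chromosome 1, 91415977 to 91459351) rose to 39.7 ± 3.40 from 2.48 ± 0.535 CPM (3.99, SE 0.24, adjusted p = 1.8e-07), and Nr1d1 fell to 33.4 ± 10.1 from 279 ± 16.5 CPM. Npas2 fell by 3.79 (SE 0.27) and Arntl by 1.51 (SE 0.22), and the clock list held 8 raised and 5 lowered of 20 (adjusted p = 0.60 with an estimated correlation). Slc25a25 rose by 3.10, Nr4a3 by 2.75, Hspa1b by 2.48 and Cys1 by 2.28, and Pfkfb3, a regulator of glycolysis, fell to 122 ± 48.2 from 784 ± 82.4 CPM. Glucocorticoid responsive genes were at 14 raised and 1 lowered of 23, Glul by 2.10 and Tsc22d3 by 1.35 (adjusted p = 0.14 with an estimated correlation). Immediate early genes rose in 12 of 27, Ier3 by 1.73, ribosome biogenesis genes in 11 of 24, antioxidant genes in 8 of 18 with 1 lowered, and heat shock genes in 10 of 27 with 1 lowered. Lipogenesis and sterol genes were at 1 raised and 9 lowered of 20, Sqle by -2.28 and Insig1 by -0.99 (SE 0.073). These 5 lists had adjusted p = 0.20 to 0.32 with an estimated correlation. Endothelial markers fell in 5 of 9 members, Cldn5 by 1.17, fibroblast markers in 4 of 11, Fbn1 by 1.67 (SE 0.15), and macrophage markers in 4 of 10 (adjusted p = 0.20, 0.32 and 0.75 with an estimated correlation). Ppargc1a did not pass (0.70, adjusted p = 0.051) but did without night wheel ZT16 replicate 1 (0.82) or 4 (0.80).

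Day wheel muscle gave another picture between ZT4 and ZT16. Nr4a3 fell by 3.59 (SE 0.47), Ppargc1a to 33.7 ± 0.873 from 144 ± 39.4 CPM and Pdk4 to 129 ± 49.3 from 634 ± 210 CPM. Mid1ip1, a regulator of lipid synthesis, rose to 71.4 ± 8.72 from 17.0 ± 1.88 CPM and Fmo2 to 28.9 ± 2.20 from 9.17 ± 1.35 CPM. Clock genes moved in part as by night, with Nr1d1 lower by 2.54 (log2 fold change -2.54, SE 0.18), Npas2 by 2.27 (-2.27, SE 0.26) and Arntl by 0.77 (-0.77, SE 0.22, adjusted p = 0.034), and Per2 rose by 0.76 (SE 0.20). Heat shock genes fell in 13 of 27 members, Serpinh1 by 0.81, immediate early genes in 8 of 27 with 1 raised, and endoplasmic reticulum and stress genes in 11 of 25 with 3 raised, Hsp90b1 by 0.44 (SE 0.049). Ribosome biogenesis genes rose in 9 of 24, and the glucose list held 7 raised and 3 lowered of 31, Tbc1d1 up by 1.37. Each of these 5 lists had an adjusted p of 0.39 with an estimated correlation. Of 17 myokines 4 fell, and of 22 amino acid catabolism genes 4 rose and 1 fell, neither list passing camera (adjusted p = 0.098 and 0.32).

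From ZT4 to ZT16, 2729 genes changed in night wheel muscle (1367 raised, 1362 lowered; 2264 without overlap of libraries, against 21.3% of all tested genes) and 2159 in day wheel muscle (1118 raised, 1041 lowered; 1919, against 20.3%). The schedules shared 408 raised genes (105.2 by independence) and 325 lowered ones (97.6), with 159 in opposite directions (202.8). With the endothelial score as a covariate 669 genes passed in night wheel muscle, and Nr4a3 (3.28), Pfkfb3 (-2.47), Arntl (-0.74) and Cldn5 (-0.53) did not. In day wheel muscle Pdk4 (-2.18) lost its call without day wheel ZT16 replicate 2, and Per2 without day wheel ZT4 replicate 1 (0.73), without day wheel ZT16 replicate 2 (0.69) and in the fit of 8 libraries (0.76). Arntl lost its call without any 1 of 7 of the 8 libraries (-0.82 to -0.71; it was kept only without day wheel ZT4 replicate 3).

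The test of the difference between these time effects passed for 1415 genes, 679 with a higher and 736 with a lower ZT16 to ZT4 ratio by day. Slc9a3r2 (gene identifier 65962, chromosome 17, 24639281 to 24650305) had the smallest p (log2 difference -1.49, SE 0.096, adjusted p = 5.5e-08), reading 31.3 and 47.3 CPM at ZT16 and ZT4 by day and 46.4 and 24.9 CPM by night. It was followed by Mcf2l (-1.46), Zfp512b (0.81) and Nfe2l2 (-0.96, SE 0.086). Nr4a3 differed by -6.35 (SE 0.67), Hspa1b by -3.61, Per2 by -3.22 (SE 0.30), Ppargc1a by -2.79 (SE 0.32) and Abra by -2.22 (SE 0.27). Lower differences by day came in 12 of 27 immediate early genes (adjusted p = 0.026 with an estimated correlation), 8 of 23 glucocorticoid responsive genes (0.047), 5 of 22 mechanical stress genes (0.036) and 19 of 27 heat shock genes (0.080). Maff differed by -1.93, Ccn2 by -1.79 and Tsc22d3 by -1.12. Clock genes were at 2 higher and 8 lower of 20 (adjusted p = 0.26 with an estimated correlation), and Arntl (0.74, adjusted p = 0.17), Nr1d1 (0.52, adjusted p = 0.21) and Dbp (-0.34, adjusted p = 0.45) did not pass. Higher differences by day came in 7 of 20 lipogenesis and sterol genes (adjusted p = 0.15), Sqle by 2.45 and Insig1 by 0.87 (SE 0.10), and in 3 of 9 endothelial markers (adjusted p = 0.21), Cldn5 by 1.27. With the endothelial score as a covariate 548 genes passed, 164 higher and 384 lower by day, and Tsc22d3 (-1.06), Sqle (2.36) and Cldn5 (0.60) did not. Nr1d1 passed without night wheel ZT16 replicate 4 (0.73).

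Of the lists of other cells of muscle, those below moved little in the treadmill comparisons. In quadriceps, erythroid, tendon and Schwann cell lists held no called gene in any of the 4 treadmill comparisons in edgeR, and at most 4 members of any list at an unadjusted p under 0.05 and 1 in DESeq2. Lymphocyte markers held 1 raised gene of 5 at +0h of each session, the fibroblast list none at +0h or +3h (at most 3 raised of 11 at an unadjusted p under 0.05, 0 in DESeq2). Smooth muscle and pericyte markers held 1 lowered gene of 8 at +0h of each session. Fast fibre genes rose in 3 of 12 members at +3h of the ZT12 session.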

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

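The tests against sedentary ZT4 muscle, of the correlation between the adipocyte and lipogenesis scores and of the endothelial markers were chosen only after the result was seen, and so was the use of list scores as covariates.

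Mitochondrially encoded transcripts were lower at +0h of the ZT0 session, with a median log2 fold change of -0.52 over 13 transcripts against sedentary ZT0 muscle. Against sedentary ZT4 muscle the median was -0.0457 and 2 transcripts were lower, which is in line with high values in the sedentary ZT0 group, whose median lay 0.49 above that of sedentary ZT4 muscle with 1 transcript passing. More slow fibre in the sedentary ZT0 libraries was argued against as the whole cause, since with the slow fibre score as a covariate the median stayed at -0.47 (median SE 0.11) and 10 transcripts passed. At +0h of the ZT12 session the median was -0.10. A time of day effect in sedentary muscle, uneven sampling of the sedentary ZT0 mice and an effect of the run itself stay open, as no test here separates them.

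Adipocyte markers and lipogenesis genes varied together in quadriceps, although the 10 adipocyte markers share 0 genes with the other lists and their medians at +0h of the ZT0 and ZT12 sessions (1.73 and -1.40) did not pass with an estimated correlation (adjusted p = 0.44 and 0.57). Over the 24 quadriceps libraries the deviations of both scores from their group means correlated at Pearson r = 0.91 (permutation p = 0.00013) and Spearman rho = 0.89 (permutation p = 0.00015; 100000 permutations within groups, 1 correlation computed), with r = 0.85 without the 2 libraries farthest from the median, which is consistent with adipose tissue in differing amounts in the dissected muscles. Without treadmill +0h ZT0 replicate 2, in which Cfd read 105 CPM against 651 and 571 CPM in the other libraries of its group, 322 genes differed between the +0h responses, 28 higher and 294 lower in the ZT12 session. With the adipocyte score as a covariate in that fit edgeR called 0 genes (565 at an unadjusted p under 0.05, 2533 without the covariate). With each gene signed by its direction without the covariate, the median log2 difference of the 322 genes went from 1.48 to 0.46. Their median SE was 0.34 both times, so the calls ended because the differences shrank. The 322 genes were picked by their calls without the covariate, which by itself favours some shrinkage. A change of lipid synthesis within the muscle fibres was not tested apart from differing amounts of adipose tissue and stays open.

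Endothelial markers were lower in day wheel muscle at ZT4, with a median of -0.33 over 9 markers. A lower share of endothelial cells would move all markers by about the same amount, but the values ran from -0.94 to -0.10 and the median lay within 2 SE of 4 of the 9 markers, which argues against it as the whole cause. With the endothelial score as a covariate the genes called at ZT4 went from 1907 to 256. With each of the 1907 genes signed by its direction without the covariate, their median log2 fold change went from 0.37 to 0.34. Their median SE went from 0.086 to 0.15. At ZT4 the score was 4.63 ± 0.0943 in day wheel and 4.99 ± 0.0521 in night wheel muscle without overlap (4.65 and 4.61 at ZT16), so that it nearly followed the schedule at ZT4, and the calls ended mainly because the spread grew. A smaller change in the share of these cells and a change of gene expression within them may both be present and were not told apart.

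The responses of the sessions differed at +3h by the test of the difference itself, which picked out 240 genes. With sedentary muscle of the session start as the control 201 passed, only 17 of them shared and 5 of these opposite in direction, and of the genes named next only Pnrc1 kept both its call and its direction. Among the named genes the log2 differences, ZT12 minus ZT0 session, were -2.46 for Banp, 1.37 for Cecr2, 1.92 for Slc43a1, 1.06 for Pnrc1, 2.44 for Pdk4, 1.93 for Fbxo32, 1.42 for Sgk1 and 1.09 for Cpt1a. They were -0.70 for Hsp90b1, -0.63 for Hyou1, -1.02 for Manf, 1.35 for Dbp and -1.47 for Nfil3. Of the 60 drawn splits, which exchanged ZT labels within the sedentary and within the treadmill libraries, 4 gave as many genes (highest other 441), so chance could not be excluded by this test. The highest of them exchanged all 3 sedentary pairs and 1 treadmill pair, an arrangement that adds the time of day effect of the sedentary groups to the contrast by construction; what drove the count was not tested.

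The time effects of the wheel schedules differed for 1415 genes by the same kind of test. The differences, day minus night wheel, were -6.35 for Nr4a3, -3.61 for Hspa1b, -3.22 for Per2, -2.79 for Ppargc1a, -2.22 for Abra, -1.93 for Maff, -1.79 for Ccn2, -1.49 for Slc9a3r2 and -1.46 for Mcf2l. They were -1.12 for Tsc22d3, -0.96 for Nfe2l2, 0.81 for Zfp512b, 0.87 for Insig1, 1.27 for Cldn5 and 2.45 for Sqle. The splits here exchanged schedule labels within ZT4 and within ZT16, so they asked whether the schedule mattered at either time. Of 60 splits 1, the real one, gave as many genes (highest other 327). At that share, not corrected over the comparisons, chance assignment to a schedule was unlikely, but these splits did not single out the difference of time effects.

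Single libraries lay far from the other 3 of their group in 15 of 208 sets of 4 gastrocnemius values examined, where chance gives about 1 in 20. In night wheel ZT4 muscle these were Clock at 33.2 CPM in replicate 2 (others 29.7 to 30.3), Tbc1d1 at 48 in replicate 4 (38.8 to 39.2), Zfp512b at 31.3 in replicate 3 (29.4 to 29.7) and the total of replicate 4, 70033483 counts (others 45010256 to 46866257). In night wheel ZT16 muscle they were Maff at 3.68 CPM in replicate 3 (2.48 to 2.62), Wdr90 at 2.73 in replicate 4 (3.35 to 3.44) and Zfp36 at 10.6 in replicate 4 (11.6 to 11.8). In day wheel ZT4 muscle they were Dbp at 51.9 in replicate 4 (38.5 to 39.3), Hspa5 at 164 in replicate 2 (170 to 171) and Nhs at 2.27 in replicate 2 (1.73 to 1.78). In day wheel ZT16 muscle they were Dbp at 54.2 in replicate 2 (39.8 to 40.4), Fbn1 at 16.9 (24.5 to 25.5), Hsp90b1 at 73.3 (81.3 to 82.7), Mid1ip1 at 84.4 (66.1 to 68) and Zfp36 at 6.66 CPM (8.19 to 8.44), the last 4 in replicate 1.

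For the other comparisons the splits gave the following. The 10 splits of 6 libraries are too few for a share under 0.05: the real counts were 1029 and 695 genes at +0h of the ZT0 and ZT12 sessions, 2052 and 2602 at +3h and 2436 for sedentary ZT12 against ZT0, and the highest other split gave 0 genes in each. Of 60 splits across the 4 sedentary groups 1, the real one, gave as many genes (2578; highest other 464). Of 35 splits of 8 wheel libraries 1, the real one, gave as many genes in each comparison that follows. For day against night wheel the real and highest other counts were 1907 and 0 at ZT4, and 82 and 17 at ZT16. For ZT16 against ZT4 they were 2729 and 2 by night, and 2159 and 6 by day. A chance split was unlikely in each at that share, which was not corrected over the comparisons. These splits cannot tell schedule or time from anything else that the mice of a group shared. For the difference of the +0h responses the real count was 0, so all 60 splits gave as many. The highest gave 1138 genes with 2 of the 3 treadmill pairs and none of the sedentary pairs exchanged, an arrangement in which the time of day effect no longer cancels, by construction, and which points to that structure of the samples; what else added to the count was not tested.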

How the results depend on the processing

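The tests with sedentary ZT4 muscle in place of ZT0 and with a list score as a covariate were chosen only after the result was seen. With DESeq2's size factors and with no filter on low counts each of the 17 counts of genes stayed within 1.5 times, and 256 and 255 of the 256 named gene results kept their side of the threshold. At the depth of the first lane alone 2 of the 17 counts moved by over 1.5 times. Small changes were limited by depth and by the 3 or 4 mice a group. For the difference of the +3h responses the self-test recovered 29.9% of log2 changes of 0.5, outside the genes of lowest level. The cause of the shifts below was not tested except where stated; a fit of fewer libraries has less information on the spread by construction.

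When only the compared groups were fitted, 529 genes passed at +0h of the ZT0 session, 385 at +0h of the ZT12 session, 1105 at +3h of the ZT0 session, 1 for the difference of the +0h and 113 for that of the +3h responses, 1597 for sedentary ZT12 against ZT0 and 35 for day against night wheel at ZT16. The genes raised and lowered in both sessions were then 179 and 21 at +0h and 303 and 226 at +3h. DESeq2 called 16 and 435 genes for the differences of the +0h and +3h responses, 102 lowered in both sessions at +0h and 369 at ZT16 between the wheel schedules. The first lane alone gave 118 genes for the difference of the +3h responses and 40 lowered in both sessions at +0h. With the adipocyte score as a covariate the counts were 590 and 450 at +0h of the ZT0 and ZT12 sessions and 1144 for sedentary ZT12 against ZT0; with the endothelial score they were 256 and 164 between schedules at ZT4 and ZT16, 669 for night wheel muscle over time and 548 for the difference of the time effects. With sedentary ZT4 in place of ZT0, 2 genes differed between the +0h responses and 1026 between sedentary ZT12 muscle and ZT4.

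Directions turned as follows, with camera's adjusted p under the alternative. With sedentary muscle of the session start as the control, the difference of the +3h responses turned for immediate early (0.425), heat shock (0.814) and mechanical stress genes (0.00776), for Banp (0.69), Cecr2 (-0.35), Cpt1a (-0.60), Dbp (-2.65), Nfil3 (0.97) and Slc43a1 (-0.41), and Dbp turned at +3h of the ZT0 session (1.23). The raised share of that difference was 63.7% against 40.8%. More genes were also raised than lowered in the fit of the compared groups (64 and 49). The same held without treadmill +3h ZT12 replicate 1 (97 and 78) or 2 (60 and 49), or sedentary ZT4 replicate 2 (59 and 48) or 3 (58 and 57). Leaving out any other library kept more lowered genes. The mechanical stress list also turned without treadmill +3h ZT0 replicate 1, at 0.990 in a range of 1.93e-07 to 0.990 over the libraries left out. With sedentary ZT4 in place of ZT0 the core clock list turned at +0h of the ZT0 session (0.409) and mitochondrially encoded genes in the difference of the +0h responses (0.981). The adipocyte score turned lipogenesis (0.188) and heat shock genes (0.937) in that difference, and the endothelial score ribosome biogenesis genes between schedules at ZT4 (0.980).

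Leaving out each library in turn gave 390 to 1317 genes at +0h of the ZT0 session, 380 to 659 at +0h of the ZT12 session, 1380 to 1784 and 1724 to 2303 at +3h, 0 to 322 and 107 to 235 for the differences of the +0h and +3h responses, 1558 to 2527 across sedentary groups and 1283 to 2350 for sedentary ZT12 against ZT0. In gastrocnemius the ranges were 1139 to 1650 and 19 to 163 between schedules at ZT4 and ZT16, 1969 to 2632 and 1682 to 1962 over time by night and by day, and 1021 to 1567 for the difference. Genes raised and lowered in both sessions ranged over 185 to 280 and 34 to 83 at +0h and over 400 to 551 and 279 to 434 at +3h. A group left with fewer mice was assumed to vary like the others.

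The replicate numbers did not pair the mice: deviations of libraries of the same number correlated at a mean of -0.00382 in quadriceps and 0.00975 in gastrocnemius, and 8 of 24 and 7 of 16 libraries lay closest to one of their own number. With the number as a replicate block the counts were 928, 655, 1979 and 2524 for the treadmill comparisons in the order above, 0 and 216 for the differences, 2400 and 2316 for the sedentary groups, and 1793, 89, 2576, 2102 and 1349 for the wheel comparisons. Of the named genes 1 changed its call, Nr4a3 at ZT16 between schedules (-2.51).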

Other observations

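Of the tests in this part, that of the clock slope was chosen only after the result was seen.

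Immediate early genes also differed between sedentary groups that had not run. Of 28 members 9 passed the test of any difference among the 4 sedentary groups, or 14 adjusted over the list alone. Junb read 5.10 ± 0.372 CPM at ZT0, 28.8 ± 14.0 at ZT4, 8.62 ± 0.856 at ZT12 and 9.74 ± 7.88 at ZT16 (SD, n = 3 each; edgeR's quasi-likelihood test, adjusted p = 0.0037). Egr3 was also highest at ZT4, at 11.1 ± 6.14 against 1.09 ± 0.393 CPM at ZT0 (adjusted p = 0.0013), and so was Arc, at 6.05 ± 2.03 against 1.40 ± 0.426 CPM (adjusted p = 0.014), whereas Ier3 was highest at ZT16 (9.84 ± 1.49 CPM, adjusted p = 0.010), a call lost without sedentary ZT16 replicate 2. Fos did not pass (adjusted p = 0.25) and read 29.1, 81.7 and 66.4 CPM in the ZT4 libraries and 28.5, 42.8 and 99.3 CPM in those of ZT16. In the treadmill +3h ZT0 group, Fos read 200, 29.9 and 3.71 CPM and Hspa1a 1153, 358 and 132 CPM in replicates 1, 2 and 3, while Nr4a3 lay between 113 and 133 CPM and Ppargc1a between 227 and 254 CPM in the same libraries.

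Day wheel muscle at ZT4 may carry the change seen 3 h after a treadmill session, a hypothesis drawn from the immediate early and heat shock genes that were higher there. Of the genes raised in both +3h responses in quadriceps, 534 were measured in gastrocnemius; their median log2 fold change in day against night wheel muscle at ZT4 was 0.11, with 135 raised and 10 lowered (limma's camera with an estimated correlation, p = 0.0044, adjusted over the 16 tests of this family p = 0.036). The 436 genes lowered in both responses had a median of -0.18, with 14 raised and 130 lowered (camera with an estimated correlation, p = 0.010, adjusted p = 0.054, which misses the threshold). The end of a session was read in the same way: 289 genes raised in both +0h responses had a median of 0.1065 (estimated correlation p = 0.042) and 65 lowered genes a median of -0.28, with 2 raised and 20 lowered (p = 0.016), and both failed the correction (adjusted p = 0.084 and 0.064). At ZT16 those 289 genes had a median of -0.18, with 0 raised and 15 lowered (adjusted p = 0.036). The immediate early and heat shock genes behind the hypothesis were not removed from these sets, so the ZT4 tests partly rest on that same observation. These libraries separated neither the schedule from the time since the last run nor a likeness to +3h from one to +0h.

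A smaller difference between ZT16 and ZT4 across the core clock in day wheel muscle is a hypothesis on the same libraries. Over the 15 clock genes called within either schedule, the slope of the day wheel on the night wheel log2 fold changes was 0.415 (0.321 to 0.519 leaving out each gene in turn), a description across genes, which are not independent replicates. The change was smaller by day in 13 of the 15 and of opposite sign in 5, among them Bhlhe41, which fell by 0.67 by night and rose by 0.63 by day, while Nr1d1 (-3.06 and -2.54) and Npas2 (-3.79 and -2.27) kept more of their change. The 13 were those called by night, whereas Cry1 (0.22 and 0.49) and Ciart (0.51 and -1.36) were called by day alone. Picking genes by their calls in these libraries favours such an outcome, so the slope and the count do not decide the hypothesis. With samples at ZT4 and ZT16 alone, a shift in phase and a lower amplitude could not be told apart.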
